A study of Mus musculus with 19 samples.

How the data were processed

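RNA was sequenced from 19 mouse liver tumor samples in 5 groups, named here as the labels name them. MYC_HCC and MYC_Twist1_HCC hold 5 libraries each, and MYC_OFF, MYC_Recur and MYC_Twist1_OFF hold 3 each. HCC stands for hepatocellular carcinoma, the tissue given for every sample. The labels give no treatment or time point for OFF or Recur. Per the labels, the 10 MYC_HCC and MYC_Twist1_HCC libraries are re-analysed from an earlier series and the other 9 are new, so group and deposit coincide in a comparison of an HCC group with MYC_OFF, MYC_Recur or MYC_Twist1_OFF. Per the labels' protocols, tumors were flash frozen, RNA was taken with a Qiagen RNeasy kit and libraries were made by standard BGI methods. The labels do not say whether the samples of a group came from separate animals, so p-values measure the spread between these samples.

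The authors deposited 1 table of normalized signal values per gene symbol, with 2 decimals and 1 column per sample. Per the submitters' processing notes, Trimmomatic, STAR, Picard, featureCounts and DESeq2 were used with the mm10 genome; versions, settings, the annotation and the formula behind the values are not given in the sources used here. The deposited values are not whole numbers, so they are not raw counts. They do not sum to a fixed total and their unit is not given, and the sequencing depth of each library is unknown. No counting interval or detection floor can therefore be given. If reads were divided between genes by shared sequence, genes with near-identical copies are uncertain, and whether strand was used in counting is not given. The table held 19511 symbols. Of these, 25 were bare numbers and were left out, since they name no gene, which left 19486 genes, 162 of them at 0 in every library. Symbols are in capitals in the table and are printed in mouse style where the symbol matched the mouse gene names (18142 symbols); NGFRAP1 and FBXO18 are printed as deposited. Genes that every cell uses are also listed at 0 in single libraries, so a 0 is given as listed, with library values. Coordinates are those of the GRCm38 assembly, the one mm10 names, from the GENCODE annotation of that assembly.

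Values were used as deposited. A gene was tested if its value was at least 1 in at least 3 libraries, which left 13253 genes. Group differences were tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(value + 1), in 1 fit of the 5 group means with 14 residual degrees of freedom; p-values are two-sided and Benjamini-Hochberg adjusted per comparison, and a change is called at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. Group values are mean ± SD of deposited values. The design written before the data were examined planned a count test as the main test and named this limma test for normalized values; the values needed the latter. The 7 comparisons were MYC_Twist1_HCC against MYC_HCC, MYC_OFF against MYC_HCC, MYC_Twist1_OFF against MYC_Twist1_HCC, MYC_Recur against MYC_OFF, MYC_Recur against MYC_HCC, MYC_Twist1_OFF against MYC_OFF, and the interaction, which is the OFF difference in the Twist1-labelled groups minus that in the MYC groups.

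Before the data were examined, 33 gene lists were written from textbook markers (metabolism, cell cycle, MYC targets, liver function, and markers of other cell types). The 13 mitochondrially encoded genes were not in the table, so 32 lists were tested with limma's camera at a preset correlation of 0.01, adjusted over all 224 tests of list and comparison. Camera was also run with the correlation estimated from the data, with the same adjustment. Every list that passed at the preset value then gave the same adjusted p, which is shared through the adjustment. It shows that none passed and does not measure single lists. Of 795 list genes, 608 were tested. Named genes follow a rule fixed beforehand: Myc and Twist1 first; then, per comparison, the 8 largest rises and 8 largest falls (5 and 5 for the interaction) among called genes with non-overlapping library values (not asked for the interaction), a mean of at least 2.59 in one of the groups compared (the 40th percentile of all values above 0) and no predicted or clone symbol; then up to 4 members of a described list with the smallest p, and 1 more where members went both ways. Some genes that this rule names are not reported here. Genes named in the closing section outside this rule were chosen after their values were seen.

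Both steps were tested on simulated data, with 200 genes shifted among 13253 in each comparison. The shifted genes were drawn only from those above a bound on the mean log2 value, so recovery of low genes was not measured. The share of 4-fold changes recovered was 97% for MYC_Twist1_HCC against MYC_HCC, 90% for MYC_OFF against MYC_HCC, 79% for MYC_Twist1_OFF against MYC_Twist1_HCC, 84% for MYC_Recur against MYC_OFF, 85% for MYC_Recur against MYC_HCC, 78% for MYC_Twist1_OFF against MYC_OFF and 52% for the interaction. For 2-fold changes it was 51%, 36%, 47%, 21%, 35%, 27% and 8% in the same order, and the share of false calls was 5.99%, 7.33%, 3.7%, 5.31%, 3.91%, 6.84% and 1.56%, above the nominal 5% in 4 of the 7. In the list test, the shifted list was called in 7 of 7 runs and 0 other lists were called. Simulated genes were drawn independently of each other, so this could not test calls that arise from correlation between genes. Alternatives were 4 scalings (by library total, upper quartile, median of ratios, and trimmed mean of M values with 30% of M and 5% of A trimmed on each side), pseudocounts of 0.1 and 5, other filters, fits of fewer groups, a replicate block, an added bound of 1 on the log2 fold change, leaving out each library, and leaving out MYC_HCC 4 and 5 together. The last, the trimmed-mean scaling of the values and the list tests with each library left out were chosen after seeing the data. Sequence copies were sought with minimap2 2.31, and figures were drawn with matplotlib 3.10.9.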

Results

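Gene expression was measured in 19 mouse liver tumors of 5 groups, 5 libraries each of MYC_HCC and MYC_Twist1_HCC and 3 each of MYC_OFF, MYC_Recur and MYC_Twist1_OFF. Deposited values summed to between 507868 and 690310 per library. The 10 genes with the highest values took 6.95% to 8.56% of the total in MYC_HCC, 8.43% to 12.7% in MYC_Twist1_HCC and 7.75% to 12.4% in MYC_Recur, against 21.0% to 28.8% in MYC_OFF and 22.6% to 26.7% in MYC_Twist1_OFF. The first principal component held 54.5% of the variance. It ran from -78.8 to -57.7 in MYC_HCC, from -45.4 to -5.5 in MYC_Twist1_HCC, from -53.4 to -34.7 in MYC_Recur, from 87.4 to 111.3 in MYC_OFF and from 95.0 to 109.8 in MYC_Twist1_OFF. On the second component, which held 10%, MYC_HCC 4 lay at -93.3 and MYC_HCC 5 at -34.3, and the other 3 MYC_HCC libraries lay between -14.0 and -4.5. In MYC_HCC 4 and 5 the noncoding RNA genes Bc1 (189.8 and 414) and Rn7sk (9.17 and 3.16), chosen after seeing the data, were lower than in the other 3, where they lay between 4587 and 6115 and between 49.6 and 55.1. No 2 libraries of a group held identical values.

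**Figure D1:**
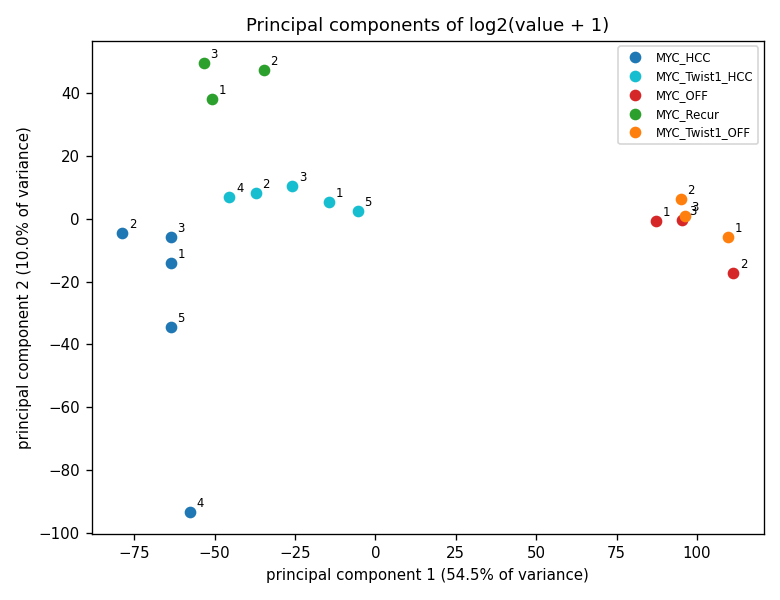
Principal components of log2(value + 1) over the tested genes, 1 point per library, coloured by group and numbered by replicate. The OFF groups lie at 87.4 and above on the first component and the other libraries at -5.5 and below.

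Myc, the oncogene the groups are named for (chromosome 15, 61985391 to 61990374), stood at 160 ± 19.2 in MYC_HCC (SD, n = 5), 125 ± 19.3 in MYC_Twist1_HCC (n = 5) and 156 ± 3.14 in MYC_Recur (n = 3), and at 45.7 ± 13.1 in MYC_OFF and 39.7 ± 6.65 in MYC_Twist1_OFF (n = 3 each). It was lower in MYC_OFF than in MYC_HCC by limma (log2 fold change -1.81, SE 0.20, adjusted p = 7.25e-07) and lower in MYC_Twist1_OFF than in MYC_Twist1_HCC (-1.63, SE 0.20, adjusted p = 6.48e-06). It was higher in MYC_Recur than in MYC_OFF (1.78, SE 0.22, adjusted p = 5.59e-06). No difference was called between MYC_Recur and MYC_HCC (-0.03, SE 0.20, adjusted p = 0.955) or between MYC_Twist1_HCC and MYC_HCC (-0.35, SE 0.17, adjusted p = 0.207). The direction of the 3 called differences was the same under all 4 other scalings, but their size moved: MYC_OFF against MYC_HCC ranged from -1.85 to -1.22, MYC_Twist1_OFF against MYC_Twist1_HCC from -1.60 to -1.15 and MYC_Recur against MYC_OFF from 1.09 to 1.69. Twist1, the transcription factor named in 2 of the groups (chromosome 12, 33957671 to 33959829), was at most 0.12 in the libraries labelled MYC_Twist1 and at most 0.27 in any library, a level under the test's filter. The values therefore do not show the labelled difference in Twist1, and each direction below between groups labelled with and without Twist1 rests on the labels.

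**Figure D2:**
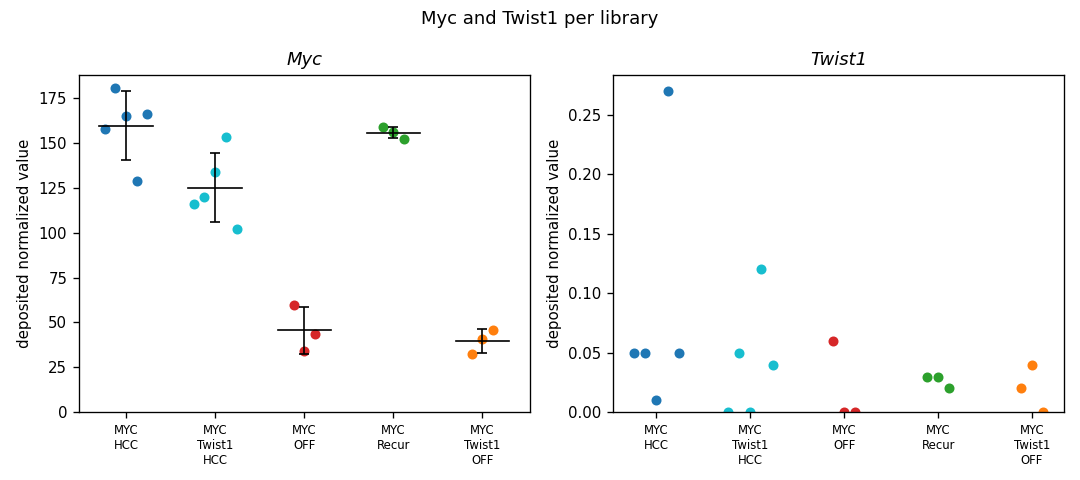
Deposited values of Myc and Twist1, 1 point per library; for Myc the line and bar give the mean and SD. Myc lay between 32.6 and 59.8 in the 6 OFF libraries and at 102 or more in the other 13, and Twist1 was at most 0.27.

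The first comparison asked how tumors labelled MYC/Twist1 differed from MYC tumors. As lists, at camera's preset correlation only, genes of mature liver function were lower in MYC_Twist1_HCC. Fgb and Fga, which encode fibrinogen chains, were at 466 ± 91.4 and 244 ± 50.5 against 1290 ± 468 and 649 ± 303 in MYC_HCC (n = 5 each; log2 fold changes -1.41 and -1.31, limma adjusted p = 0.00691 and 0.0199). Albumin (Alb) fell from 2407 ± 1262 to 1113 ± 279 (-1.01, limma adjusted p = 0.0448). Of the 26 mature hepatocyte genes tested, 4 fell and none rose, or 7 and none adjusted over the list alone; the median was -0.93 and camera gave an adjusted p = 5.93e-05, which became an adjusted p = 0.994 with an estimated correlation. Among single genes, the largest rises were of Rsl1 (4.76, from 1.35 ± 0.65 to 75.1 ± 49.3), Gcnt1 (4.26), Robo1, a guidance receptor (3.95), Apod (3.82), Brpf3 (3.80), Hspb7 (3.67), Srms (3.59) and Foxa2, a transcription factor of liver and gut (3.58, from 7.77 ± 5.15 to 118 ± 75.9). The largest falls were of Sh3d19 (-3.95; listed at 0 in 4 MYC_Twist1_HCC libraries and at 16.9 in the other), Dda1 (-3.79), Rfc1, a subunit of replication factor C (-3.79), Ccdc124 (-3.69), the nucleolar protein gene Npm1 (-3.35, from 3220 ± 1142 to 331 ± 150) and Sap30 (-3.25). Xpo4 and Dennd1a were listed at 0 in all 5 MYC_Twist1_HCC libraries, and lay between 3.7 and 11.9 and between 4.77 and 15.01 in MYC_HCC. Some of these differences were not particular to the Twist1 label. MYC_Recur, labelled without Twist1, also differed from MYC_HCC in Gcnt1 (4.58), Foxa2 (4.06) and Ccdc124 (-4.38). Rfc1 lay at 1.33, 1.09 and 11.86 and Dda1 at 0.18, 0.34 and 0.48 in MYC_Recur 1, 2 and 3. Others did not follow in every library: Robo1 was at 2.65 in MYC_Recur 1, within the range of MYC_HCC.

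In MYC_Twist1_HCC against MYC_HCC, 424 genes were higher and 428 lower of 13253 tested. Other liver lists were also lower by camera, each with an adjusted p = 0.994 with an estimated correlation: 27 complement and coagulation genes (0 rose, 2 fell, also 2 adjusted over the list alone; adjusted p = 0.0141), among them plasminogen (Plg, -0.95) and factor IX (F9, -1.77, at 41.7 in MYC_HCC 4 and at most 8.03 in the other MYC_HCC libraries), 20 fatty acid oxidation genes (0 rose, 2 fell, the same number adjusted over the list alone; adjusted p = 0.0165), among them Acadl (-1.02), and 16 bile acid genes (0 rose and 1, Hsd3b7 at -0.66, fell, as when adjusted over the list alone; adjusted p = 0.0237). None of 24 cytochrome P450 and drug metabolism genes was called, also when adjusted over the list alone, with a list adjusted p = 0.0249, or adjusted p = 0.994 with an estimated correlation; Cyp2e1 was at 60.3 ± 7.55 against 99.1 ± 30.3 and Gstm1 at 75.2 ± 14.8 against 154 ± 106. MYC_HCC 4 stood apart in these genes: without it, the complement, fatty acid, bile acid and P450 lists gave adjusted p = 0.327, 0.148, 0.59 and 0.636, and the hepatocyte list 0.0215, which became 0.0584 without MYC_HCC 4 and 5. The P450 list also gave 0.0513 without MYC_Twist1_HCC 2 and 0.0512 without MYC_Twist1_HCC 4, and with these 2 groups fitted alone it gave 0.0863 and the bile acid list 0.0794. The other 27 lists gave adjusted p from 0.0514 to 0.981. Single genes of these lists passed. Utp20 and Gnl3, of ribosome biogenesis, rose (1.13 and 0.97), whereas Npm1 of the same list fell. Rises were also seen in the mitotic kinesin Kif20a (1.36) and the cyclin gene Ccne2 (1.04), while Rrm2 (-0.76), Tgfb1 (-0.87) and Fn1 (-1.20) fell. Many single calls named here were lost when 1 or another single library was left out: those of Alb, F9, Hsd3b7, Plg, Fga, Rrm2, Kif20a, Ccne2, Gnl3, Tgfb1, Fn1, Npm1, Hspb7 and Srms. With each of the 10 libraries left out in turn, Npm1 lost its call 9 times and Fn1, Ccne2, Rrm2 and Srms 8 times each. Alb and Hspb7 lost it 7 times each, and the others from 2 (Fga) to 6 times (F9 and Tgfb1). Those of Alb and F9 were also lost with the median of ratios, the upper quartile and the trimmed mean of M values. Without MYC_HCC 4 and 5, Fgb, Gcnt1 and Utp20 were no longer called. The number of called genes was 389 without MYC_Twist1_HCC 1, 404 without MYC_Twist1_HCC 5, 467 without MYC_HCC 5 and 352 without MYC_HCC 4 and 5.

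**Figure D3:**
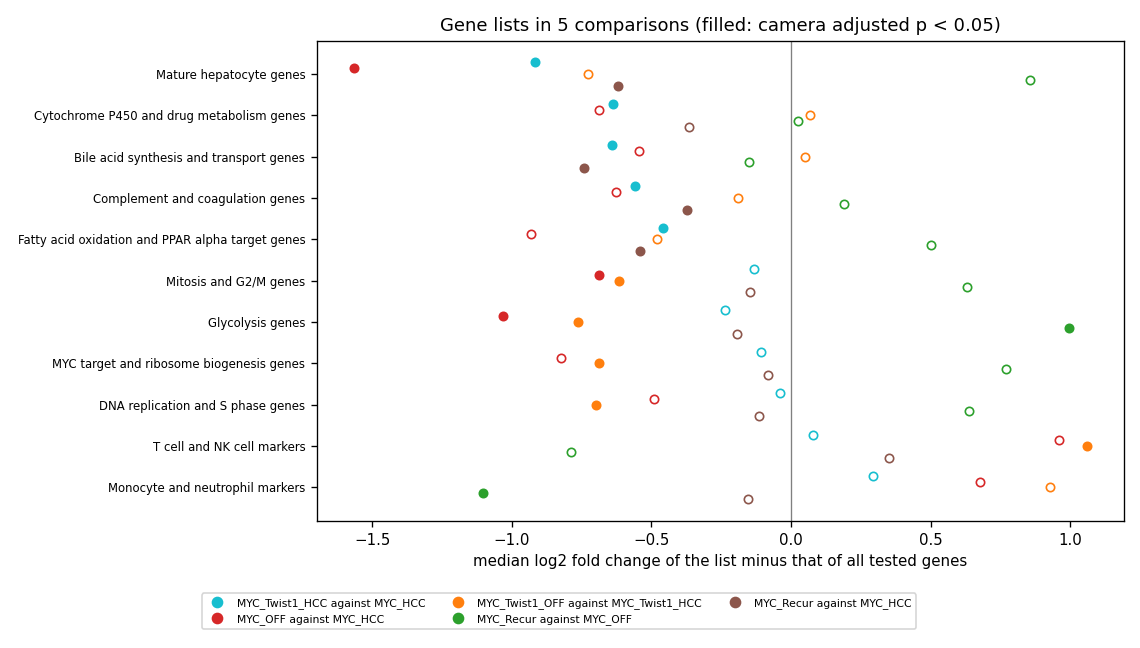
Median log2 fold change of each gene list minus the median of all tested genes, in 5 comparisons (colours), for the lists with a camera adjusted p under 0.05 in any of them (filled points mark that p, which was 0.994 for each with an estimated correlation). Mature hepatocyte genes lay 1.57 below the median of all genes in MYC_OFF against MYC_HCC, and glycolysis genes 1.03 below it.

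The comparison of MYC_OFF with MYC_HCC asked how tumors labelled OFF differed from MYC tumors. Hepatocyte, glycolysis and mitosis genes were lower in MYC_OFF as lists, at camera's preset correlation only. Albumin was at 321 ± 80.4 against 2407 ± 1262 (log2 fold change -2.79, SE 0.34, limma adjusted p = 2.09e-06), transthyretin (Ttr) fell by 2.55, Serpina1c by 3.62 and apolipoprotein B (Apob) by 1.84. Of 26 hepatocyte genes 21 fell and none rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00953, or adjusted p = 0.994 with an estimated correlation). Of 18 glycolysis genes 14 fell and none rose, also adjusted over the list alone (adjusted p = 0.0204, or adjusted p = 0.994 with an estimated correlation); Pgk1 fell from 436 ± 39.9 to 85.0 ± 6.67, Aldoa by 2.27, Gpi1 by 2.81 and Tpi1 by 2.68 on the log2 scale. Of 30 mitosis genes 20 fell and 3 rose, or 20 and 4 adjusted over the list alone (adjusted p = 0.0422, or adjusted p = 0.994 with an estimated correlation): Aurkb (-2.69), Ccnb1 (-3.50), Mki67 (-2.12) and Prc1 (-2.20) fell, whereas Racgap1, a regulator of cell division, rose from 26.2 ± 12.7 to 441 ± 319 (3.95). The mitosis list gave 0.0582 with these groups fitted alone, 0.0596 without MYC_HCC 5, 0.0523 without MYC_OFF 1 and 0.0501 without MYC_Twist1_HCC 2. The last library enters the shared estimate of the spread, and its own comparisons enter the adjustment over all list tests.

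The MYC target and ribosome biogenesis list missed the threshold (adjusted p = 0.0637), although 25 of its 38 genes fell and 3 rose, with the same counts adjusted over the list alone. Nop58 (-2.38) and Mybbp1a (-2.10) fell, and the mitochondrial folate enzyme gene Mthfd2 rose (6.0, from 14.5 ± 9.79 to 980 ± 806). DNA replication genes (adjusted p = 0.06) had 20 falls and 2 rises among 30, also adjusted over the list alone; Ccne1 fell by 4.0 and Rrm2 by 2.64. Without MYC_HCC 4 both lists passed, with adjusted p = 0.0411 and 0.0338. The keratin genes Krt18 and Krt8, whose proteins pair in liver filaments, went opposite ways: Krt18 rose from 131 ± 70.9 to 1980 ± 102 (4.09) and Krt8 fell from 163 ± 73.1 to 24.9 ± 14.4 (-2.73). The largest rises were of Rsl1 (8.43, from 1.35 ± 0.65 to 815 ± 276), the palmitoyltransferase gene Zdhhc16 (8.43), Pdlim5 (7.40), Robo1 (7.19), Cox6b2 (6.83), the histone gene Hist2h3c1 (6.79), Ap5z1 (6.75) and the transcription factor gene Tfap4 (6.45). The largest falls were of Hmgn5 (-5.44; listed at 0 in MYC_OFF 2 and 3 and at 14.7 in MYC_OFF 1), the Mediator subunit gene Med25 (-4.98; at 0 in the same libraries and 0.84 in MYC_OFF 1), Mcee (-4.98), Ccdc124 (-4.93), the proteasome subunit gene Psma6 (-4.92, from 184 ± 47.1 to 5.39 ± 3.10), protein C (Proc, -4.86), Ube2c (-4.84) and Gldc (-4.70).

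In all, 2511 genes were higher and 5221 lower in MYC_OFF, that is 32.5% of calls higher. The median of all tested genes was -0.38. Scaling by the trimmed mean of M values moved it to 0.02, with 3691 genes higher and 3686 lower (50% higher); the median of ratios and the upper quartile each gave 53% higher. The medians of the 3 passing lists stayed below 0 under all 4 other scalings, while their size and counts moved: with the median of ratios the mitosis median went from -1.07 to -0.53 (-0.52 with the upper quartile), with 14 falls and 4 rises, 17 hepatocyte genes fell and 1 rose, and 11 glycolysis genes fell and none rose. The 2 groups come from different deposits, and no value within 1 deposit can be had for this comparison. Of the 1747 genes over 4-fold from the median here, 8.76% lay as far the same way in MYC_Recur against MYC_HCC, also new against re-analysed libraries. Of all 13253 tested genes, 344 lay that far either way in MYC_Recur against MYC_HCC, a smaller share.

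**Figure D4:**
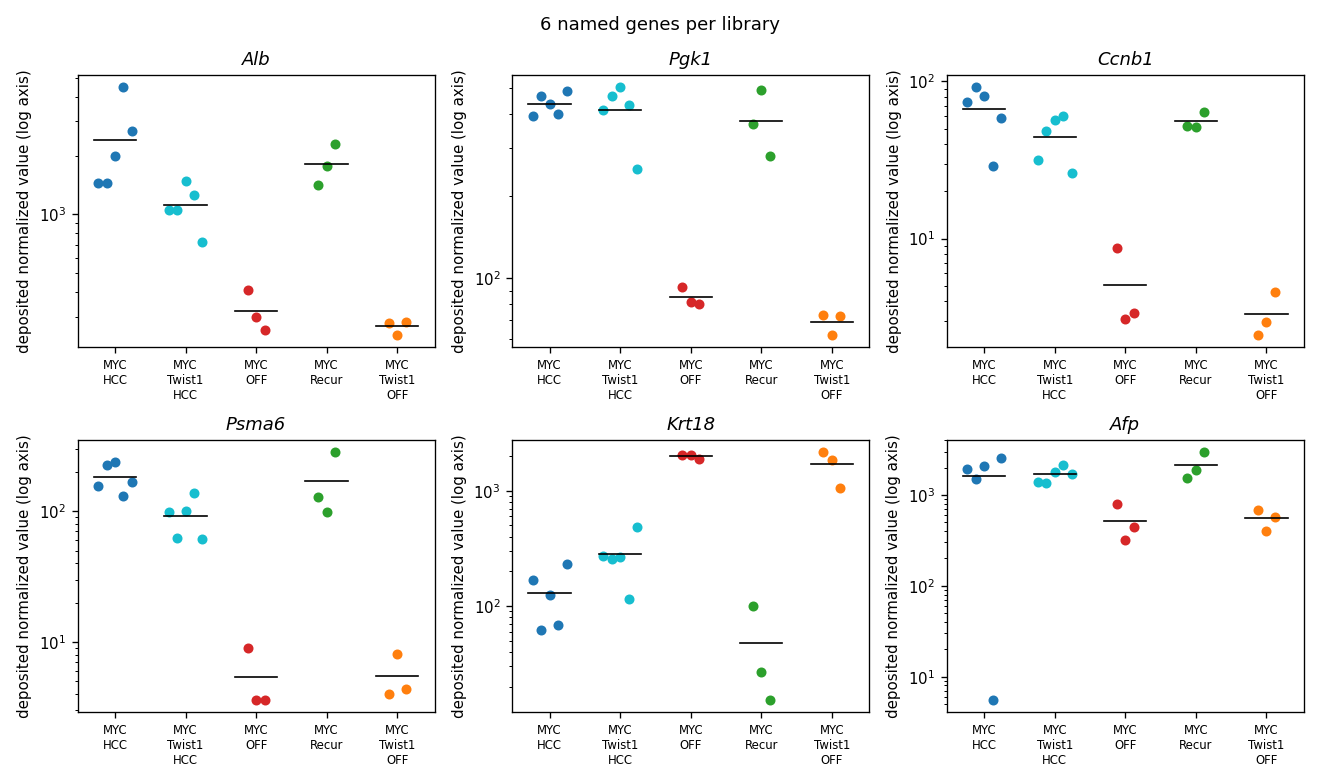
Deposited values (log axis) of 6 genes, 1 point per library, with the arithmetic group mean as a line. Alb, Pgk1, Ccnb1 and Psma6 were lower and Krt18 higher in both OFF groups than in their HCC groups; Afp was at 5.55 in MYC_HCC 4 and at 318 or more elsewhere.

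MYC_Twist1_OFF was compared with MYC_Twist1_HCC in the same way. As lists, at camera's preset correlation only, MYC target, replication, mitosis and glycolysis genes were lower in MYC_Twist1_OFF and markers of T and NK cells were higher, the last with 3 of 12 members called. Of 38 MYC target genes 25 fell and 1 rose, or 26 and 1 adjusted over the list alone (camera adjusted p = 0.0249, or adjusted p = 0.994 with an estimated correlation): Nop58 fell from 125 ± 24.6 to 29.4 ± 5.51 (-2.04, limma adjusted p = 2.7e-06), nucleolin (Ncl) by 2.68 and Pes1 by 1.63, and Mthfd2 rose (4.16). Of 30 replication genes 21 fell and none rose, or 21 and 1 adjusted over the list alone (adjusted p = 0.0165, or adjusted p = 0.994 with an estimated correlation), including Ccne1 (-3.65), Rrm1 (-2.34), Prim1 (-1.61) and Rrm2 (-1.80). Of 30 mitosis genes 21 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.0249, or adjusted p = 0.994 with an estimated correlation): Ccnb1 (-3.36), Aurkb (-2.25), Ube2c (-3.91) and Mki67 (-1.63) fell and Racgap1 rose (2.42). Of 18 glycolysis genes 13 fell and none rose, also adjusted over the list alone (adjusted p = 0.0165, or adjusted p = 0.994 with an estimated correlation); Pgk1 fell from 413 ± 96.3 to 69.1 ± 6.36 (-2.53), Aldoa by 2.32, Pfkl by 1.70 and Pdk1 by 2.13. Of 12 T and NK cell markers 3 rose and none fell, or 1 and none adjusted over the list alone (adjusted p = 0.0237, or adjusted p = 0.994 with an estimated correlation): Cd8b1 rose from 0.234 ± 0.18 to 2.03 ± 1.54, Ccl5 from 1.18 ± 0.65 to 3.53 ± 0.62 and Lck from 2.11 ± 0.88 to 4.82 ± 0.62; Cd3d was at 1.15 ± 0.31 against 0.33 ± 0.14 and missed the threshold (adjusted p = 0.0514). The T and NK cell list holds 30 genes, and only the 12 that passed the filter on low values were tested. A gene could pass it through the 3 libraries of an OFF group alone. The members named here lay low in MYC_Twist1_HCC and had little room to fall, while the median of all tested genes was -0.32. The rise of this list may therefore rest in part on its low level. Of 16 stellate cell and fibroblast markers 5 rose and none fell, also adjusted over the list alone, with a median of 0.29, and the list missed the threshold (camera adjusted p = 0.0512). The MYC target list gave 0.054 without MYC_HCC 4 and 5. The calls of Racgap1, Ccl5 and Lck were lost without any 1 of several libraries, that of Cd8b1 without MYC_Twist1_OFF 1 and that of Mthfd2 without MYC_Twist1_OFF 3.

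The largest rises here were of Tfap4 (7.91, from 5.26 ± 6.08 to 1254 ± 719), the magnesium transporter gene Slc41a1 (6.32), Zfp719 (5.99), Zdhhc18 (5.89), Erf (5.86), Pdlim5 (5.60), the casein kinase gene Csnk1a1 (5.59) and Mul1 (5.45). Erf lay at 4095, 113 and 16.2 and Csnk1a1 at 1947, 138 and 10.3 in MYC_Twist1_OFF 1, 2 and 3, and neither was called without MYC_Twist1_OFF 1. The largest falls were of NGFRAP1 (-5.06), Abracl (-4.76, from 38.0 ± 7.68 to 0.417 ± 0.10), the splicing factor gene U2af1 (-4.68), Anp32e (-4.65), the pyruvate dehydrogenase subunit gene Pdhb (-4.63), Nqo2 (-4.61), Itm2b (-4.49) and Mcee (-4.29). In all, 1732 genes were higher and 4446 lower (28.0% higher), around a median of all genes of -0.32. The trimmed mean of M values gave 2707 higher and 2951 lower (47.8%), the median of ratios 52.4% and the upper quartile 52.8%; the medians of the 5 lists kept their sign under all 4. The counts of list members moved with the scaling: with the median of ratios, 14 MYC target genes fell and 6 rose, 12 mitosis genes fell and 3 rose, 14 replication genes fell and 1 rose, 8 glycolysis genes fell and none rose, and 6 T and NK cell markers rose and none fell. The trimmed mean of M values gave 16 and 4, 16 and 3, 17 and 1, and 9 and none for the first 4 lists, and 6 rises for the last; the upper quartile gave 11 falls of mitosis genes and 2 rises of replication genes, and otherwise the counts of the median of ratios. Group and deposit coincide here too. Against the first OFF comparison, with which it shares no library, 1460 genes were higher in both and 4000 lower in both, where independent lists would share 328.2 and 1751.5, and 3 went opposite ways. Across the 13253 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.90.

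MYC_Recur and MYC_OFF, both new libraries, were compared next. Glycolysis genes were higher in MYC_Recur: 13 of 18 rose and none fell, or 14 and none adjusted over the list alone (camera adjusted p = 0.0249, or adjusted p = 0.994 with an estimated correlation). Pgk1 rose from 85.0 ± 6.67 to 379 ± 105 (n = 3 each; log2 fold change 2.11, SE 0.25, limma adjusted p = 4.06e-06), Aldoa by 2.11, Gpi1 by 2.71 and the glucose transporter gene Slc2a1 by 2.25 on the log2 scale. Monocyte and neutrophil markers were lower as a list (median -0.65, adjusted p = 0.0458, or adjusted p = 0.994 with an estimated correlation), with 5 of 13 falling and 2 rising, also adjusted over the list alone. The receptor gene Csf3r fell from 43.5 ± 33.1 to 1.10 ± 0.95 (-4.07) and Itgam by 1.41, while S100a9 (2.90) and Plac8 (1.74), of neutrophils and monocytes, rose. The monocyte list gave an adjusted p = 0.154 with trimmed-mean scaling and 0.0572 with scaling by library total. It gave 0.0806 without MYC_Recur 1, 0.0563 without MYC_Recur 3 and 0.0693 without MYC_OFF 2. Without MYC_HCC 4, MYC_Twist1_HCC 4 and MYC_Twist1_HCC 5 it gave 0.0803, 0.0508 and 0.0507. The HCC libraries enter the shared estimate of the spread, and their own comparisons enter the adjustment over all list tests. Plac8 was not called with the median of ratios or the upper quartile.

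Among the 30 lists that missed the threshold (adjusted p from 0.0699 to 0.99) were mitosis genes (0.0699), of which 23 rose and 3 fell, also adjusted over the list alone: Aurkb (2.61), Ccnb1 (3.34) and Ube2c (4.57) rose and Kif20a fell from 93.6 ± 31.4 to 9.09 ± 1.33 (-3.19). The hepatocyte genes Alb (2.50), Apoa1 (2.14) and Hpd (2.13) rose, and Krt18 fell from 1980 ± 102 to 47.7 ± 46.4 (-5.78). The largest rises were of the exchange factor gene Kalrn (6.72; 71.6 to 138 in MYC_Recur and at most 0.06 in MYC_OFF), Ubac2 (5.99), Veph1 (5.51), Adh5 (4.98), Pdhb (4.90), Tma7 (4.75), the spindle checkpoint gene Bub3 (4.74) and Psma6 (4.70). The largest falls were of Tfap4 (-9.65, from 1542 ± 1799 to 0.14 ± 0.04), Fam207a (-7.46, from 693 ± 102 to 3.17 ± 1.87), the autophagy kinase gene Ulk1 (-7.39), Pias1 (-7.32), Zdhhc18 (-7.19), Rhbdf2 (-7.03) and Slc41a1 (-7.03). Ccdc130, whose fall (-7.77) ranked next after that of Tfap4, was listed at 0 in all 3 MYC_Recur libraries and at 500, 379 and 53.8 in MYC_OFF. In all, 4964 genes were higher and 1585 lower (75.8% higher), around a median of 0.45. The trimmed mean of M values gave 2976 and 2765 (51.8%), the median of ratios 46.6% and the upper quartile 50.1%, and the median of the glycolysis list, 1.45, lay between 0.82 and 1.37 under all 4 other scalings, with 9 to 13 genes rising.

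MYC_Recur was also compared with MYC_HCC, across deposits. Kalrn was at 113 ± 35.8 in MYC_Recur against 1.47 ± 1.39 in MYC_HCC (n = 3 and 5; log2 fold change 5.66, SE 0.50, limma adjusted p = 4.1e-06). Rises of Nkain3 (5.36), Veph1 (5.31), Gcnt1 (4.58), Plekha1 (4.27), the erythroid transcription factor gene Klf1 (4.16) and Foxa2 (4.06, from 7.77 ± 5.15 to 136 ± 58.1) followed. The largest fall was of Acsl3 (-5.12), listed at 0 in all 3 MYC_Recur libraries and between 21.3 and 53.1 in MYC_HCC. Med25 (-4.98), Ccs (-4.48), Ccdc124 (-4.38), the kinase gene Map2k2 (-4.29), Sephs1 (-4.15), Get4 (-4.05) and Hibch (-4.05) had the next largest falls. Of single list genes, the heme and globin genes Alas2 (0.92) and Hbb-b1 (2.56; listed at 0 in MYC_HCC 4 and 5 and between 11.3 and 15.3 in the others) rose, and the mitosis gene Kif20a (-1.95) fell. Of 38 MYC target genes 2 fell, Wdr12 (-1.43) and Hspd1 (-2.05), and Utp20 rose (0.93, adjusted p = 0.0458), or 2 and none adjusted over the list alone. Of 30 replication genes 2 fell, among them Pcna (-1.21), and Dut rose (0.89), also adjusted over the list alone. Neither list passed. The rise of Utp20 was not called under any of the 4 other scalings or without any 1 of several libraries, and that of Dut was not called without MYC_Recur 1 or 3. Without MYC_Recur 3, Gcnt1, Hibch, Alas2, Pcna and Hspd1 (then -1.02) were no longer called, and the calls of Plekha1, Acsl3 and Hbb-b1 were lost without any 1 of the 3 MYC_Recur libraries and without some MYC_HCC libraries.

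Liver lists were lower in MYC_Recur by camera: 26 hepatocyte genes (adjusted p = 0.00953), 16 bile acid genes (0.0165), 20 fatty acid oxidation genes (0.0217) and 27 complement and coagulation genes (0.0237), each with an adjusted p = 0.994 with an estimated correlation. Without MYC_HCC 4 they gave 0.167, 0.452, 0.248 and 0.53 in this order, and the complement list gave 0.0549 with these groups fitted alone. Of all their members 1 was called, C3 of the complement cascade, which fell from 564.2 ± 464 to 138 ± 16.7 (-1.68, adjusted p = 0.024); it was at 1319.6 and 695 in MYC_HCC 4 and 5 and at most 312 in the other 3. Adjusted over the list alone it was again the only call, and it was lost without any 1 of the 3 MYC_Recur libraries, without MYC_HCC 5 and with these groups fitted alone. Apob was at 53.3 ± 3.49 against 92.1 ± 32.6, Hnf4a at 62.4 ± 1.88 against 102 ± 19.3, Hadha at 37.7 ± 11.2 against 121 ± 67.0, Acadm at 133 ± 48.5 against 243 ± 114 and Slc10a1 at 14.3 ± 3.43 against 59.1 ± 82.3, none of them called; Slc10a1 was at 206 in MYC_HCC 4 and at most 26.9 in the other MYC_HCC libraries. The other 28 lists gave adjusted p from 0.0512 to 0.99. In all, 914 genes were higher and 521 lower (63.7% higher); scaling by library total gave 52.7% and the median of ratios 50.7%. The number of called genes was 819 without MYC_Recur 3, 917 without MYC_Recur 2 and 835 without MYC_HCC 4 and 5.

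MYC_Twist1_OFF and MYC_OFF, both new, differed in 1 called gene by limma, with 330 genes at an unadjusted p under 0.05. Mllt1, a subunit gene of elongation complexes (chromosome 17, 56892611 to 56935415), was listed at 0 in MYC_Twist1_OFF 1 and 3 and at 5.76 in MYC_Twist1_OFF 2, against 187, 61.7 and 361 in MYC_OFF 1, 2 and 3 (log2 fold change -6.42, SE 0.85, adjusted p = 0.00725). No list passed (32 tested, adjusted p from 0.485 to 0.981). No gene was called when these 2 groups were fitted alone, and 21 were called without MYC_OFF 3, 3 without MYC_OFF 2, 2 without MYC_OFF 1 and 0 without MYC_Twist1_OFF 3. Mllt1 was not called without MYC_Twist1_OFF 1 or without MYC_Twist1_OFF 3. In the self-test of this comparison, which shifted no low genes, 27% of 2-fold changes were recovered.

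The interaction tested whether the OFF difference itself differed between the Twist1-labelled and the MYC groups; an equal shift between deposits cancels in it. It was called for 13 genes, 3 upward and 10 downward. Rsl1 (-4.18, SE 0.70, limma adjusted p = 0.0282) rose in both OFF comparisons, from 1.35 ± 0.65 to 815 ± 276 in the MYC groups and from 75.1 ± 49.3 to 1222 ± 413 in the Twist1-labelled groups. FBXO18 (-5.02), the phosphorylase kinase gene Phkg1 (-3.63), the lysophosphatidic acid receptor gene Lpar2 (-3.02) and Mogat1 (-2.32) were the other large downward terms among genes without a predicted symbol. Mean Lpar2 was 58.2 in MYC_OFF and 62.1 in MYC_Twist1_OFF, and mean Mogat1 was 7.42 and 6.65. Lpar2 was at most 1.27 in MYC_HCC and at least 5.52 in MYC_Twist1_HCC. Mogat1 was at most 2.9 and at least 5.16 there. The terms of Lpar2 and Mogat1 therefore rest on the difference between the HCC groups. Upward terms were those of Vipas39 (3.61), Xpo4 (3.20) and Jun, of the AP-1 transcription factor (2.49). Jun lay between 13.5 and 29.7 in MYC_HCC and at 7.91 or less in the other 3 groups. Xpo4 was listed at 0 in every library of these 3 groups, and Vipas39 in all but MYC_Twist1_HCC 4 (2.46) and MYC_Twist1_OFF 1 (2.43). A gene at 0 cannot fall further, so these 2 terms are no measure of a different OFF change. Jun was limited in a like way: it was at 0, 0.95 and 0 in MYC_OFF 1, 2 and 3 and at most 1.78 in MYC_Twist1_OFF. It started lower in MYC_Twist1_HCC than in MYC_HCC and so had less room to fall. Hepatocyte genes (camera adjusted p = 6.5e-05), bile acid genes and acute phase genes (0.0249 each) had upward terms as lists, each with an adjusted p = 0.994 with an estimated correlation and with no member called, also adjusted over the list alone; Fga (1.33), Nr1h4 (1.05) and Serpina3k (1.89) had adjusted p from 0.57 to 0.639. Without MYC_HCC 4 the lists gave 0.0176, 0.53 and 0.553. The bile acid list also gave 0.163 without MYC_OFF 1, 0.0995 without MYC_Twist1_OFF 1, 0.0652 without MYC_Twist1_OFF 3 and 0.0512 without MYC_Twist1_HCC 4, and the acute phase list 0.0826 without MYC_OFF 1 and 0.0649 without MYC_Twist1_OFF 1. Each of the 7 genes named here other than Xpo4 lost its call without 1 or another of several single libraries, from 5 (Vipas39) to 11 (Phkg1) and 14 of them (Mogat1). With these 4 groups fitted alone, 8 genes were called, and 18 of 100 splits with the Twist1 label shuffled within HCC and within OFF, the real one included, called at least as many. The number of called genes was 49 without MYC_OFF 1, 7 without MYC_OFF 2 or MYC_HCC 5, 3 without MYC_Twist1_OFF 3 and 1 when any single one of MYC_Twist1_HCC 1, MYC_Twist1_HCC 5, MYC_Twist1_OFF 1 and MYC_Twist1_OFF 2 was left out, and it was 5 without MYC_HCC 4 and 5.

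Genes of 2 families, ribosomal proteins and proteasome subunits, were taken by symbol and compared in the OFF groups. Of 78 ribosomal protein genes, 55 were lower and 9 higher in MYC_OFF than in MYC_HCC, with log2 fold changes from -3.84 to 5.37. Of 39 proteasome subunit genes, 24 were lower and 7 higher, from -4.92 to 2.22. Under the 4 other scalings the ribosomal counts ranged from 37 to 58 lower and from 9 to 11 higher, and the proteasome counts from 18 to 25 lower and from 7 to 10 higher. In MYC_Twist1_OFF against MYC_Twist1_HCC, 59 ribosomal protein genes were lower and 6 higher (-3.01 to 2.65), and 21 proteasome genes were lower and none higher (-3.83 to 0.76). The other scalings gave 47 to 60 lower and 6 to 9 higher, and 18 to 20 lower and 0 to 2 higher. The SD among the ribosomal protein genes of 1 library, as log2 change from the MYC_HCC mean, was 0.17 to 0.31 in MYC_HCC, whose own libraries make that mean, 0.47 to 1.39 in MYC_Twist1_HCC, 0.46 to 0.93 in MYC_Recur, 1.36 to 1.71 in MYC_OFF and 1.59 to 1.94 in MYC_Twist1_OFF. These families were chosen after seeing the data. A symbol does not show that a gene's product is part of 1 complex. The same SD over all tested genes was not computed, so a spread particular to these families is not shown.

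**Figure D5:**
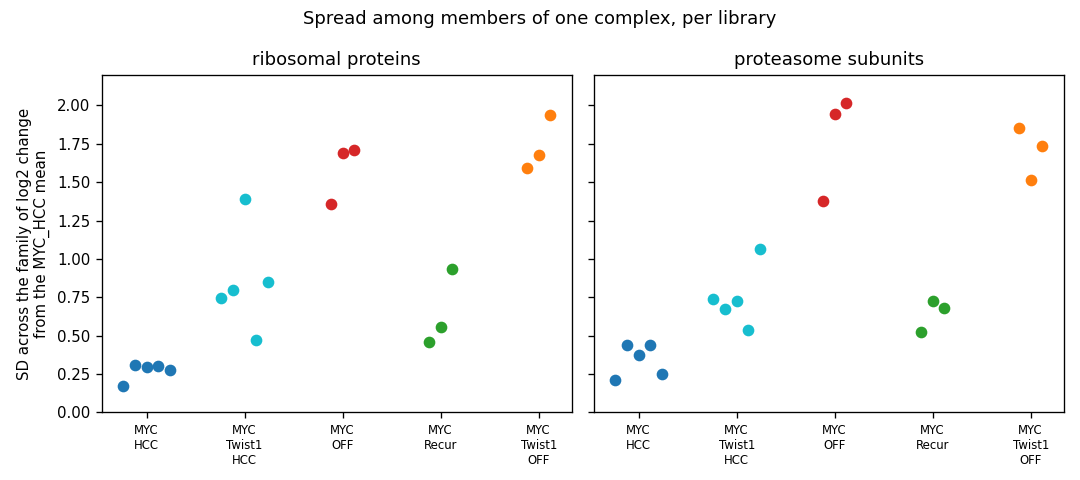
SD among the members of 2 gene families taken by symbol, 78 ribosomal protein and 39 proteasome subunit genes, of the log2 change from the MYC_HCC mean, 1 point per library. The OFF libraries lie at 1.36 and above for the ribosomal proteins and at 1.38 and above for the proteasome.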

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

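Tests of library composition, sequence copies, deposit and labels, and the shuffle of Twist1 labels, in this part were chosen after the results were seen. Within groups of 5 libraries, a library was picked out where its gap to the nearest other library took an unusually large part of the group's range (Dixon's bound). Over the genes named in the text and the library measures, 33 of 280 such sets of 5 passed the bound, where chance alone gives about 14, since about 1 in 20 groups is picked out by chance. The sets share libraries, and many of the genes were named for their large changes, so they are not independent and the chance number is only a guide.

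MYC_HCC 4 accounted for 11 of the 33. It was higher than the other 4 MYC_HCC libraries in Acadm (440.5, others at most 218.1), Apob (150.03), F9 (41.7), Gstm1 (342.2), Nr1h4 (60.25), Serpina1c (2077), Slc10a1 (206), Ttr (1990) and Twist1 (0.27), and lower in Gnl3 (125.5) and NGFRAP1 (27.5). Among the other MYC_HCC libraries, MYC_HCC 2 was low for Hnf4a (68.1) and at -78.8 on the first principal component, and MYC_HCC 3 was high for Dennd1a (15.01) and Rfc1 (62.8). MYC_Twist1_HCC 1 was high for Acsl3 (1212), Ccdc130 (75.95), Gcnt1 (449), Hspb7 (153.8), Mllt1 (6.35), Mul1 (15.49), Slc41a1 (4.82), Tfap4 (15.85) and Ulk1 (11.31). MYC_Twist1_HCC 2 was high for Brpf3 (860) and Hibch (39.78) and low for Hnf4a (50.31), MYC_Twist1_HCC 3 was high for Ap5z1 (80.97), MYC_Twist1_HCC 4 was high for FBXO18 (95.12), Sh3d19 (16.89) and Vipas39 (2.46), and MYC_Twist1_HCC 5 was high for Hspd1 (2208.7) and low for Aurkb (14.45).

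The limma interaction of the Twist1 label with the OFF difference was called for 13 genes. With its 4 groups fitted alone it was called for 8, and 18 of 100 splits with the Twist1 label shuffled within HCC and within OFF, the real one included, called at least as many. This shuffle also breaks the Twist1 difference within HCC, so it is no fair reference, and chance is not excluded. The terms were 3.203 for Xpo4, 3.611 for Vipas39, 2.493 for Jun, -2.262 for Abracl, -1.946 for Chmp4c, -4.184 for Rsl1, -3.021 for Lpar2, -3.969 for Gm12504, -5.018 for FBXO18, -1.709 for Fam160a2, -3.627 for Phkg1, -2.189 for Uqcrq and -2.317 for Mogat1. Xpo4 was at 0 in every MYC_Twist1_HCC, MYC_OFF and MYC_Twist1_OFF library and Vipas39 in nearly all, and a gene at 0 cannot fall further, so these 2 terms are no measure of a different OFF change. Jun, near 0 in both OFF groups and lower in MYC_Twist1_HCC than in MYC_HCC, also had less room to fall in the Twist1-labelled groups. Lpar2 and Mogat1 lay at like levels in both OFF groups, so their terms rest on the difference between the HCC groups. Median terms of 0.851 for hepatocyte genes, 0.699 for bile acid genes and 0.749 for acute phase genes also passed by camera, but none of them with an estimated correlation (adjusted p = 0.994), and without MYC_HCC 4 only the hepatocyte list passed.

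The low Afp and high liver genes of MYC_HCC 4 were weighed first: Afp, the fetal liver and tumor marker, was at 0.275% of its mean in the other 4 MYC_HCC libraries, and Cyp3a11 at 1779%. Liver RNA mixed into the sample could not lower Afp that far without lowering proliferation genes alike, and the median mitosis gene was at 57.6% of the other libraries; mixing as a part of the cause of the high liver genes stays open. A library of another group under this label is argued against by its correlation with its own group, up to 0.905, against at most 0.856 with any library of another group. A library type shared with MYC_HCC 5 is argued against for the low Afp alone, by Afp at 139% of MYC_HCC 1 to 3 in that library, but it stays open for the rest, as do a sample from outside these groups and a tumor of another kind: both libraries are low in Bc1 and Rn7sk, and both are above MYC_HCC 1 to 3 in C3 (1319.6 and 695), Serpina3k (154 and 69.2) and Cyp3a11 (648 and 69.1). No biological explanation was tested.

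The large changes of single genes in MYC_OFF against MYC_HCC (1071 genes over 4-fold above the median and 676 over 4-fold below it) were weighed next. Reads shared with processed pseudogenes cannot be the whole cause, since of the 891 genes above and 634 below with a matched transcript 9.76% and 28.4% have such a copy, against 15.4% of other matched genes; matched for level, the odds ratio was 0.306 (0.24 to 0.389) above and 1.24 (1.02 to 1.5) below, so a small part may remain for the latter. After trends on length and GC content were taken off, 90.3% of the matched genes stayed over 4-fold from the median. A shift between the re-analysed and the new libraries is argued against as the whole cause by MYC_Recur, also new, in which 8.76% of these genes moved as far the same way from MYC_HCC. Of all 13253 tested genes, 344 lay that far either way there, a smaller share, so such a shift stays open as a part of the cause. MYC_HCC also enters both comparisons. A batch or RNA quality of the OFF libraries alone, and the OFF state itself, stay open, and no label separates them.

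Last, Twist1 was near 0 in libraries labelled MYC_Twist1. A swap of labels between the MYC and MYC_Twist1 groups as the cause of the low values is argued against, since no library labelled MYC alone exceeded 0.27. Transgene reads that were not counted under the gene symbol may account for the low values, at most 0.12 in the Twist1-labelled libraries, but the deposited values hold nothing that can decide this, so it cannot be told apart from a true lack of expression, and in that case Twist1 cannot check the labels at all.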

How the results depend on the processing

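Scaling by the trimmed mean of M values, leaving out MYC_HCC 4 and 5, and list tests without each library were chosen after seeing the data; the other alternatives were planned. Total counts of called genes under MYC_OFF against MYC_HCC, MYC_Twist1_OFF against MYC_Twist1_HCC and MYC_Recur against MYC_OFF stayed within 1.5 times under every alternative run. Their split into higher and lower genes did not. As deposited it was 2511 and 5221, 1732 and 4446, and 4964 and 1585 in this order. With the median of ratios it was 3920 and 3470, 2946 and 2677, and 2663 and 3052. For MYC_Twist1_HCC against MYC_HCC (852 calls), 497 had a log2 fold change of at least 1 in size, 352 were called without MYC_HCC 4 and 5, and 389 to 893 with 1 library left out. For MYC_Recur against MYC_HCC (1435), the count was 835 without MYC_HCC 4 and 5 and 819 to 1314 with 1 library left out. For MYC_Twist1_OFF against MYC_OFF (1), it was 3 with no filter on low values, 0 with a pseudocount of 0.1, 2 with a pseudocount of 5, 0 with only the groups compared, 0 with only libraries of the same deposit, and 0 to 21 with 1 library left out. In the settings that gave 0, between 180 and 455 genes had an unadjusted p under 0.05 by limma. For the interaction (13), it was 4 with no filter on low values, 7 with a pseudocount of 0.1, 8 with only the groups compared, 5 without MYC_HCC 4 and 5, and 1 to 49 with 1 library left out. Of the list tests, 22 passed, 0 with an estimated inter-gene correlation, 35 with fry, 9 without MYC_HCC 4 and 5, and 13 (without MYC_HCC 4) to 32 (without MYC_HCC 1) with 1 library left out; fry tests whether the genes of a list move, on balance, one way, and not against other genes. The P450 list of MYC_Twist1_HCC against MYC_HCC turned upward without MYC_HCC 4 and 5 (adjusted p = 0.839). Fits that leave libraries out hold fewer samples; beyond that, the cause was not tested for any of these.

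The replicate numbers were checked for pairing. In 0 of 10 pairs of groups did every pair of same-numbered libraries correlate above 0.1 in their deviations (r from -0.214 to 0.384), so no pairing was seen by this rule. Differently numbered libraries were not compared, so the rule cannot show that the samples are unpaired. With the numbers as a replicate block, MYC_Recur against MYC_HCC gave 936 calls and MYC_Twist1_OFF against MYC_OFF gave 0; the other 5 counts of genes stayed within 1.5 times. The bile acid, complement and fatty acid lists of MYC_Recur against MYC_HCC gave adjusted p = 0.0963, 0.148 and 0.056 with the block.

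Over all alternatives, single genes named in the text stayed on the same side of the threshold in 3523 cases. They lost the call in 323, gained one in 12 and reversed in none. Direction was compared only for genes called in the main fit. Most of these genes were named for large changes or small p in the same values. The lack of reversals is therefore no separate test of direction. Passing lists kept their call in 488 cases, lost it in 83 and reversed in 1. The planned count tests (the fixed main test, DESeq2 and voom) and thinning were not run, since the values are not counts. Depth is unknown, so what it limits cannot be given.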

Other observations

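Genes in this part were chosen after their values were seen, and the tests of other splits were planned, except the shuffle within HCC and within OFF. Rps19, a ribosomal protein gene, was at 26471, 32923 and 65239 in MYC_OFF 1, 2 and 3 and between 28733 and 50636 in MYC_Twist1_OFF, against 458 to 1439 in MYC_HCC and 446 to 1911 in MYC_Recur. It was at 1656 in MYC_Twist1_HCC 4 and between 5761 and 9142 in the other MYC_Twist1_HCC libraries. Rps19 has copies in the genome, so reads shared with them stay possible and the value is uncertain. The proteasome subunit gene Psma6 moved the other way, and the SD among the 39 proteasome genes was 1.38 to 2.02 in MYC_OFF and 1.52 to 1.85 in MYC_Twist1_OFF, against 0.54 to 1.06 in MYC_Twist1_HCC, 0.52 to 0.72 in MYC_Recur and 0.21 to 0.44 in MYC_HCC, whose mean is the reference. A few genes also differed widely between libraries of one OFF group: Csnk1a1 lay at 619, 7022 and 1.73 and Erf at 268, 3418 and 0.02 in MYC_OFF 1, 2 and 3.

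The gene lists that missed the threshold gave adjusted p from 0.0512 to 0.986 in MYC_Twist1_OFF against MYC_Twist1_HCC (27 lists), from 0.06 to 0.99 in MYC_OFF against MYC_HCC (29 lists) and from 0.0514 to 0.983 in the interaction (29 lists).

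Other splits of the same libraries into groups of the same sizes were fitted with those groups alone. For MYC_Twist1_HCC against MYC_HCC, 1 of 100 splits, the real one, gave as many genes (1147, and the highest other gave 2), which argues against a random split of these libraries. The same holds for MYC_OFF against MYC_HCC (1 of 56 splits; 6885 against 4), MYC_Twist1_OFF against MYC_Twist1_HCC (1 of 56; 7212 against 2) and MYC_Recur against MYC_HCC (1 of 56; 1255 against 16). In these 3 the real split is also that between the deposits, so this does not separate group from deposit. For MYC_Twist1_HCC against MYC_HCC it does not separate the Twist1 label from any other difference between those libraries. For the interaction, the planned shuffle over all 4 groups (3 of 100 splits; 8 against 11) moves the OFF difference into the residual and is no fair reference. With the Twist1 label shuffled within HCC and within OFF, 18 of 100 splits, the real one included, gave at least its 8 genes and the highest other gave 276. This shuffle also breaks the Twist1 difference within HCC, which can then enter the interaction or the residual, so it is no fair reference either. Chance is therefore not excluded for the interaction. What lies behind the split with 276 calls was not tested. For MYC_Recur against MYC_OFF (1 of 10 splits; 4913 against 0) and MYC_Twist1_OFF against MYC_OFF (10 of 10; 0 against 0), the splits are too few for a share under 5%.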
